A study of Mus musculus with 12 samples.

How the data were processed

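The data are bulk RNA sequencing counts from 12 libraries of sorted mouse cells, in 6 groups of 2. Per the labels, mice carried either Myf5-Cre or Ucp1-iCre together with a membrane reporter that turns from tdTomato to GFP in cells that have carried the recombinase and in their descendants. From each driver line came GFP-positive and GFP-negative mammary myoepithelial cells (lineage-negative, CD24-positive, CD29-high) at day 10 of lactation, and GFP-positive brown adipocytes from 8-week-old virgin females. Per the labels' protocols, RNA was isolated with an RNeasy Micro kit, cDNA was amplified with SMART-Seq v4 Ultra Low Input, and libraries were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name TopHat, HTSeq and DESeq2 and the genome build mm10. Tool versions, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The authors deposited 1 file of raw read counts per library, indexed by Ensembl gene identifier. All per-library columns of these files were used (0 were left unused).

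The files were joined on the gene identifier into 38924 genes. Symbols, gene types and positions came from GENCODE M21 (mm10), which gave a symbol to 37607 genes. The 12 genes that share a symbol with another kept their identifier as name. Processing used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. From the transcript sequences, the percent of each gene's 31-base sequences (every 10 bases) that also occur in transcripts of another gene was computed, as a measure of reads that a counting rule could split or drop. Nuclear protein-coding genes with at most 5% of such sequence number 13568.

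The library totals ranged from 11027738 to 32956480. A gene at 0 in a library therefore lies under 0.09103 to 0.27204 counts-per-million (CPM), the value of 3 counts there, which is the upper limit of the 95% interval for 0 counts. This range is on raw totals, without the TMM scaling applied to the CPM values and fold bounds. Where every library of a group held 0 counts, the fold is given as at least the mean of the other group over 3 counts in the pooled total of the empty group, never as the fitted fold. These floors cover counting error only, not variation between samples. CPM values are scaled by TMM factors and given as mean ± SD over the libraries of a group.

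Groups followed the labels. The main test was the edgeR quasi-likelihood test with TMM factors, genes kept by filterByExpr (minimum count 10), and Benjamini-Hochberg adjustment over all genes tested at 0.05. All 12 libraries entered 1 fit with a mean per group, so that groups of 2 share an estimate of the spread. The comparisons were GFP-positive against GFP-negative myoepithelial cells within each driver, GFP-positive myoepithelial cells against brown adipocytes within each driver, the difference of the GFP effect between drivers, and the drivers against each other within each cell group. Both drivers were also pooled on 8 libraries with the driver as covariate, for the GFP label and for the tissue. Every standard error of a log2 fold change is the estimate over the square root of its F statistic. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

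Within each comparison, 20 gene lists were tested with camera at the preset correlation of 0.01 and with the correlation estimated per list, adjusted over the lists with at least 5 tested members. Camera sets a list against all other tested genes, so higher, lower or upward by camera means relative to those genes. The lists were myoepithelial contractile, basal epithelial, luminal epithelial, milk, brown adipocyte thermogenic, general adipocyte, lipid synthesis, fatty acid oxidation, oxidative phosphorylation, skeletal muscle, fibroblast and preadipocyte, endothelial, pericyte, immune, erythroid, Schwann, basement membrane, cell cycle, dissociation response, and glycolysis and hypoxia. They hold 302 symbols, of which 295 were found. Counts of list members are given over all genes and adjusted over the list alone. A list member was counted as not overlapping where all libraries of 1 group lay above all of the other.

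Named genes follow a rule. They are the driver genes Myf5 and Ucp1 and the sort genes Itgb1 and Cd24a, then up to 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap, predicted genes left out. From each list come up to 4 called members of smallest adjusted p, or the 2 of highest mean CPM where none was called. Any member of the contractile, basal, thermogenic and general adipocyte lists could be named. Genes named outside the rule are marked as chosen after their values were seen.

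A brown adipocyte signature of 200 genes a side was chosen in brown adipocytes against GFP-negative myoepithelial cells of 1 driver and tested with camera in the myoepithelial libraries of the other driver. Correlation of log2 fold changes between drivers used fits on the 4 myoepithelial libraries of each driver over the genes of the 12-library fit. Library similarity is the Pearson correlation of log2 CPM with a prior count of 2.

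The groups, the comparisons, the lists, the naming rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2, limma-voom with sample weights, RLE factors, no filter, robust dispersion, a test against a fold of 2 (glmTreat), removal of milk and mitochondrial genes, only the compared groups in the fit, the replicate number as a block, each library left out, no driver covariate, other signature sizes and other prior counts. Settings added after the data were seen were a fit without the 2 Ucp1 GFP-positive myoepithelial libraries, a test over genes with at least 10 counts in both of those libraries, the correlation between drivers for the tissue comparison, and the genes of little shared sequence alone. For the pooled comparisons, all 35 splits of 4 against 4 libraries were refitted.

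The main test was tested on simulated counts with the fitted dispersion trend and 50 changed genes at each of 4 sizes. For the Myf5 label comparison it recovered 2% of 4-fold, 62% of 16-fold, 86% of 64-fold and 96% of 256-fold changes with 2 false calls, and for the Ucp1 label comparison 4%, 46%, 96% and 98% with 3 false calls. Changes of 4-fold or less were thus mostly out of reach of this design. The simulation gave all libraries the same dispersion trend and changed only genes of at least 10 CPM. It left out the wider spread and missing genes of the Ucp1 GFP-positive libraries. Its false calls therefore do not measure those among the real Ucp1 label calls. The common dispersion was 0.717, a coefficient of variation of 0.847 between samples.

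Genes that share sequence with copies, such as the casein genes, the haemoglobin genes Hba-a1 and Hba-a2, and Ly6c1, and genes that overlap or lie antisense to another are uncertain, because the counting rule is not stated. Such genes differ widely between the mammary and brown adipocyte files (described in the report), so comparisons between the tissues cannot be separated from a possible difference in counting. The single-gene result of 1 list member is not reported here. Reporter transcripts were not analysed here, and raw reads were not used here.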

Results

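The libraries held RNA from lineage-traced cells of 2 mouse lines, in which GFP marks cells that once carried Myf5-Cre or Ucp1-iCre and their descendants. Each line gave GFP-positive and GFP-negative mammary myoepithelial cells at day 10 of lactation and GFP-positive brown adipocytes from 8-week-old virgins (n = 2 libraries per group, 12 in all). Totals ran from 11027738 to 32956480 counts per library. The Ucp1 GFP-positive myoepithelial libraries stood apart: at 22313233 and 32956480 counts they held 10909 and 10560 genes with a count, against 19794 and 19213 genes in their GFP-negative partners at 30072983 and 31005011 counts. Their log2 levels correlated at only r = 0.605, and 27 of 3832 genes with a mean of at least 50 CPM were at 0 in 1 of the 2 libraries. In the other 5 groups, replicates correlated at r = 0.872 to 0.992. Mitochondrial genes took 12.6% to 36.0% of the counts in brown adipocytes and 0.648% to 2.45% in mammary libraries. The first 3 principal components held 37.96%, 25.14% and 12.3% of the variance.

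**Figure D1:**
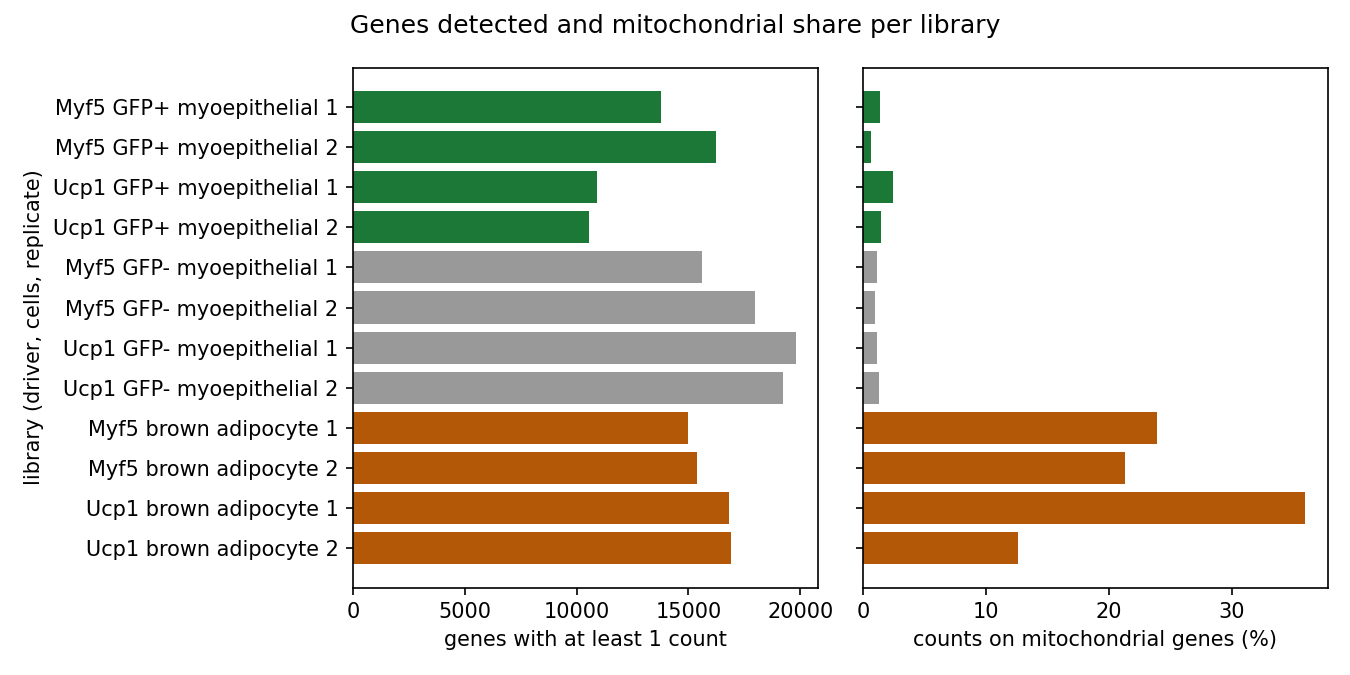
Genes with a count and percent of mitochondrial counts in each of the 12 libraries. The Ucp1 GFP-positive myoepithelial libraries held 10909 and 10560 genes, the fewest. The mitochondrial share cannot be separated from a possible difference in counting between mammary and brown adipocyte files.

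Except for Myf5 in 1 library, the driver genes were nearly silent in the sorted mammary cells. Ucp1, the uncoupling protein of brown fat mitochondria (ENSMUSG00000031710, mm10 chromosome 8, 83290352 to 83298452), had 0 counts in all 4 GFP-positive myoepithelial libraries. It had 61 and 12 counts in Myf5 GFP-negative, 18 and 18 in Ucp1 GFP-negative, and 9048 to 179375 in brown adipocyte libraries. Myf5, a myogenic transcription factor (ENSMUSG00000000435, chromosome 10, 107482908 to 107486134), had 193 counts in 1 Myf5 GFP-positive myoepithelial library, 2 in 1 Ucp1 GFP-negative library and 0 elsewhere, brown adipocytes included. Itgb1, the sort marker CD29 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200), was at similar levels with and without GFP: 608 ± 320 against 446 ± 251 CPM in the Myf5 line and 781 ± 119 against 902 ± 95.01 CPM in the Ucp1 line (SD, n = 2 each; edgeR adjusted p = 1 and adjusted p = 0.859). Cd24a, the other sort marker (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265), averaged 32.8 ± 27.8 against 70.3 ± 11.2 CPM in the Myf5 line and 8.74 ± 11.5 against 109 ± 18.1 CPM in the Ucp1 line, also without a call (edgeR adjusted p = 1 and adjusted p = 0.128).

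**Figure D2:**
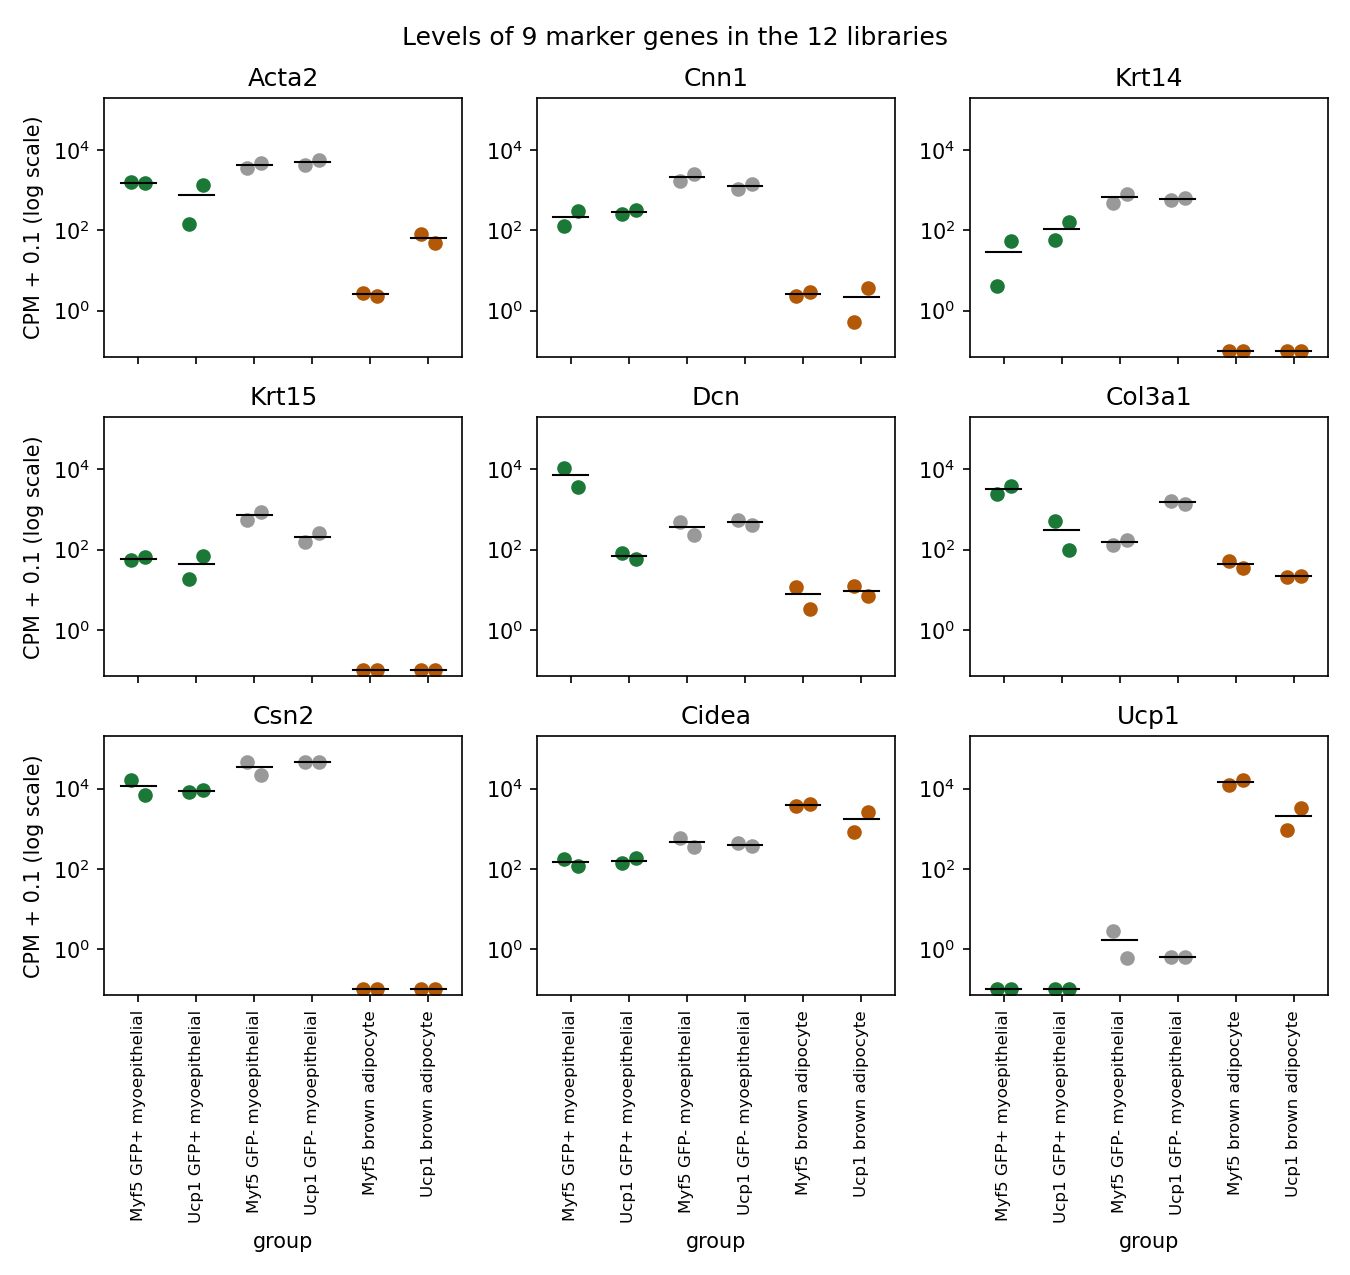
Levels of 9 genes in the 6 groups (points, libraries; lines, means; CPM plus 0.1). Ucp1 averaged 14500 CPM in Myf5 brown adipocytes and 0 CPM in both GFP-positive myoepithelial groups.

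The first question was how myoepithelial cells that carried the Myf5 label differ from unlabelled ones of the same gate. Stromal genes were the group that stood out. Decorin, a collagen-binding matrix proteoglycan (Dcn, ENSMUSG00000019929, chromosome 10, 97479609 to 97518143), averaged 7214 ± 5153 CPM in GFP-positive and 358 ± 185 CPM in GFP-negative cells (SD, n = 2 each; log2 4.33, SE 0.823). Col3a1, a fibrillar collagen chain (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), averaged 3183 ± 1027 against 152 ± 32.9 CPM (log2 4.39, SE 0.76). The fibroblast and preadipocyte list had a median log2 of 4.35, with 13 of 14 members not overlapping upward (16.7% are expected each way by chance), and 7 members rose when adjusted over the list alone. This was the clearest list result and it held under both camera settings (adjusted p = 2.3e-14, and adjusted p = 0.0029 with an estimated correlation). The pericyte list was also higher under both (median 2.39, 6 members over the list alone, adjusted p = 7.9e-09, and adjusted p = 0.03 with an estimated correlation), but without the 2 Ucp1 GFP-positive libraries the latter became an adjusted p = 0.067 (fibroblast list, adjusted p = 0.0044). Its highest members were the signalling regulators Rgs5, at 1914 ± 435 against 375 ± 131 CPM (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813), and Rgs4, at 323 ± 83.6 against 41.5 ± 9.41 CPM (SD, n = 2 each).

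Genes that define basal and contractile myoepithelial cells pointed the other way. Krt17, Krt15, Krt14 and Krt5, keratins of the basal layer, had log2 values of -4.36 (SE 0.962), -3.58 (SE 0.727), -4.50 (SE 1.2) and -4.33 (SE 0.855) in Myf5 GFP-positive over GFP-negative cells. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548) averaged 29.2 ± 35.7 against 662 ± 239 CPM, and Krt15 (ENSMUSG00000054146, chromosome 11, 100131758 to 100135928) 59.8 ± 7.42 against 713 ± 227 CPM (SD, n = 2 each). The basal list had a median of -2.91, with 13 of 18 members not overlapping downward and 1 upward, and 6 lower and 1 higher over the list alone (adjusted p = 3.8e-06, and adjusted p = 0.16 with an estimated correlation). Acta2, smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), remained abundant at 1562 ± 21.8 against 4211 ± 870 CPM (log2 -1.43, SE 0.809, edgeR adjusted p = 0.688). Calponin (Cnn1) averaged 216 ± 123 against 2146 ± 636 CPM, while the intermediate filament gene Des went upward, at 122 ± 57.7 against 14.9 ± 1.27 CPM (log2 3.03, SE 0.581, edgeR adjusted p = 0.231). The contractile list had a median of -1.16, with 1 member higher and 1 lower over the list alone (adjusted p = 0.048, and adjusted p = 0.62 with an estimated correlation). Without filtering or with milk and mitochondrial genes removed, its camera call was lost (adjusted p = 0.088 and adjusted p = 0.05). Leaving out 1 library moved its median widely, though it stayed below 0 (range given below).

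Brown adipocyte genes were mixed in these cells. Ebf2, a factor of brown preadipocytes (ENSMUSG00000022053, chromosome 14, 67233292 to 67430918), averaged 76.9 ± 13.8 against 8.46 ± 4.41 CPM (log2 3.18, SE 0.782, edgeR adjusted p = 0.289). Dio2, the thyroid hormone deiodinase, averaged 13.8 ± 13.6 against 0.0405 ± 0.0572 CPM, and Lhx8 and Zic1, markers of classical brown fat, were at least 160-fold and at least 98.0-fold higher, with 0 counts in the GFP-negative libraries. Cidea, a lipid droplet protein of brown fat, averaged 145 ± 37.2 against 478 ± 174 CPM, and Ucp1 and the proton channel Otop1 had 0 counts in GFP-positive cells (at least 23.7-fold and at least 38.3-fold lower). The thermogenic list had a median of 0.00, a mean of 1.07, 4 members higher and 3 lower over the list alone (camera upward, adjusted p = 0.52, and adjusted p = 0.82 with an estimated correlation). The general adipocyte list had a median of -0.774 (-0.627 with empty genes at their bound; adjusted p = 0.024, and adjusted p = 0.48 with an estimated correlation), led by Lipe, hormone-sensitive lipase, at 19.4 ± 1.12 against 67.0 ± 5.47 CPM (n = 2 each).

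Markers of other cell types moved with the label as well. Lower lists in Myf5 GFP-positive cells were milk (median -1.61, 5 members over the list alone, adjusted p = 1.8e-09, and adjusted p = 0.1 with an estimated correlation), luminal epithelial (-1.77, adjusted p = 0.00051 and 0.11), endothelial (-1.57, adjusted p = 0.00051 and 0.48), immune (-1.39, adjusted p = 4.2e-05 and 0.31) and erythroid (-3.04, 4 members over the list alone, adjusted p = 3.8e-06 and 0.16), the second value again with an estimated correlation. Csn2, beta-casein (ENSMUSG00000063157, chromosome 5, 87692624 to 87699630), was still 11770 ± 6833 CPM in GFP-positive and 34230 ± 17950 CPM in GFP-negative cells. No call was made for lipid synthesis (median -0.288, adjusted p = 0.2), fatty acid oxidation (-0.109, 0.39), oxidative phosphorylation (-0.12, 0.87), skeletal muscle (0, 0.45), Schwann (-1.99, 0.1), basement membrane (-0.315, 0.95), cell cycle (-0.362, 0.31), dissociation response (0.16, 0.2), or glycolysis and hypoxia (-0.201 with a mean of 0.188 and camera upward, 0.68). Of the Myf5 label lists, only the fibroblast and pericyte calls held with an estimated correlation over all 12 libraries, and only the fibroblast call also without the 2 Ucp1 GFP-positive ones.

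No single gene passed the threshold in the Myf5 label comparison of the 12-library fit: edgeR called 0 of 16953 genes, with 1573 at unadjusted p under 0.05 and a smallest adjusted p = 0.212. DESeq2 called 724 genes (486 higher) and limma-voom 197 (155 higher). Without the 2 Ucp1 GFP-positive libraries, whose spread enters the shared estimate, edgeR called 232 genes (180 higher), 6 of them in the fibroblast list, all higher. That fit also called 4 thermogenic members higher (Dio2, Lhx8, Ebf2 and Kcnk3) and Otop1 lower, and 1 basal member higher and 2 lower.

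The second question was the same for the Ucp1 label, where the result was dominated by genes missing from the GFP-positive libraries. Des, the muscle intermediate filament gene (ENSMUSG00000026208, chromosome 1, 75360329 to 75368579), fell at least 2003-fold from 87.8 ± 23.4 CPM to 0 counts (SD, n = 2; edgeR adjusted p = 0.00117). Has1, a hyaluronan synthase (ENSMUSG00000003665, chromosome 17, 17843323 to 17855205), fell at least 1614-fold and the complement gene C3 at least 1491-fold, also to 0. Ackr1, Gja5, Tmem63a, Tlr2, Tmem86a, F3 and Tmem115 fell at least 1382-, 1299-, 1209-, 1115-, 1090-, 1088- and 1037-fold. Rises were fewer and smaller. Haptoglobin (Hp, ENSMUSG00000031722, chromosome 8, 109575128 to 109579172) rose from 0.953 ± 0.224 to 17.4 ± 3.26 CPM (log2 4.18, SE 0.828, edgeR adjusted p = 0.00936). Dgat2, a triglyceride synthesis enzyme (ENSMUSG00000030747, chromosome 7, 99153658 to 99182719), rose from 8.92 ± 0.772 to 64.9 ± 35.3 CPM (log2 2.86, SE 0.728, edgeR adjusted p = 0.0302). Car3, a carbonic anhydrase abundant in fat, rose from 36.1 ± 25.4 to 300 ± 265 CPM (log2 3.05, SE 0.841, edgeR adjusted p = 0.0412). The other largest rises were Skap1 (log2 5.33), Arid3b (3.44), Atm (3.44), Socs7 (3.41), Sned1 (3.11), Lipt1 (3.07) and Simc1 (2.95).

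Contractile genes were lower in Ucp1 GFP-positive cells, and detectable in part. Tagln, the smooth muscle protein transgelin (ENSMUSG00000032085, chromosome 9, 45929619 to 45936058), fell from 1455 ± 243 to 261 ± 129 CPM (log2 -2.48, SE 0.577, edgeR adjusted p = 0.0205), and Mylk, myosin light chain kinase, from 606 ± 63.7 to 142 ± 60.7 CPM (log2 -2.09, SE 0.593, edgeR adjusted p = 0.0451). Acta2 averaged 764 ± 876 against 4949 ± 932 CPM (log2 -2.70, edgeR adjusted p = 0.0624). All 17 contractile members lay lower without overlap, 6 passed the test over all genes and 9 over the list alone (median -2.27, adjusted p = 0.0046, and adjusted p = 0.77 with an estimated correlation). Tpm1, Tpm2 and Des were among the 6, and Myocd, a coactivator of smooth muscle genes, fell at least 56.9-fold. Among basal genes none passed: Krt17 averaged 84.7 ± 77.9 against 444 ± 11.1 CPM and Krt14 109 ± 74.9 against 607 ± 27.5 CPM (n = 2 each). The basal median was -0.808 (camera upward, adjusted p = 0.81).

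Thermogenic genes went both ways with the Ucp1 label, with 7 of 17 members above 0, and over all genes 5 fell and 0 rose. Otop1 fell at least 183-fold from 8.02 ± 3.74 CPM (edgeR adjusted p = 0.00364), Dio2 at least 21.8-fold, Ucp1 at least 12.4-fold from 0.545 CPM (edgeR adjusted p = 0.0323), Slc27a2 at least 11.7-fold and Lhx8 at least 9.66-fold. Among all genes at 5 to 10 CPM in Ucp1 GFP-negative cells, 51.9% and 54.1% had under 3 counts in the first and second GFP-positive library. Missing counts at such low levels are therefore common there, and these fold bounds cover counting error only. Cidea averaged 160 ± 33.2 against 399 ± 53.3 CPM (edgeR adjusted p = 0.145), and Cox8b, a brown fat respiratory subunit, 3.83 ± 1.09 against 0.469 ± 0.144 CPM (edgeR adjusted p = 0.0553). Over the list alone 1 member was higher and 5 lower, and with RLE factors 1 was higher and 4 lower over all genes. The thermogenic median was -1.03 (-0.584 with empty genes at their bound) with camera upward (adjusted p = 0.81). This median depended strongly on single libraries but stayed below 0 with any 1 left out (range given below). Between libraries of the same number, over members with a mean of at least 1 CPM, the sign differed. The median difference in log2 of CPM plus 1 was -0.814 for the first and 1.04 for the second. In the general adipocyte list Dgat2 and Car3 rose and none fell (median 0.374, adjusted p = 0.0046, and adjusted p = 0.72 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, averaged 14.8 ± 3.17 against 2.08 ± 1.48 CPM (edgeR adjusted p = 0.0913).

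Other cell types' markers were lower too in the Ucp1 GFP-positive libraries. Milk genes had 7 called members, all lower (median -2.13, adjusted p = 0.026), such as Glycam1 (log2 -3.56, SE 0.446, edgeR adjusted p = 0.00244) and Wap, whey acidic protein (17350 ± 3079 to 3302 ± 948 CPM, edgeR adjusted p = 0.0316). Lower lists by camera were fibroblast (-2.54, 5 called, adjusted p = 0.0085; Dpt, Lum, Thy1 and Dpp4 fell), Schwann (-9.0, or -6.28 at the bounds, 5 called, adjusted p = 0.0046) and immune (-2.07, 3 called, adjusted p = 0.04; Ptprc, the leukocyte antigen CD45, fell at least 228-fold). The dissociation response (0.301, adjusted p = 0.013) and the endothelial list (0.136 with a mean of -0.168, adjusted p = 0.048) were higher by camera with no member called. Both are relative to all genes, whose median was -0.686. Of 14 endothelial members, 4 lay higher and 3 lower without overlap. With RLE factors the milk, immune and endothelial calls were lost (adjusted p = 0.051 each). No camera call was made for luminal (-1.86, 2 called, 0.37), skeletal muscle (-7.56, or -4.59 at the bounds, 3 called, 0.091), pericyte (-1.44, 0.66), erythroid (-1.66, 1 called, 0.66), basement membrane (-0.342, 3 called, 0.86), cell cycle (-1.62, 2 called, 0.66), lipid synthesis (-0.595 with camera upward, 0.81), fatty acid oxidation (-0.000288 with camera upward, 0.09), oxidative phosphorylation (-0.869, 0.81) or glycolysis and hypoxia (-0.384 with camera upward, 2 called, 0.81). No Ucp1 label call held with an estimated correlation, where the smallest was adjusted p = 0.38.

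In all, edgeR called 2423 of 16953 genes between Ucp1 GFP-positive and GFP-negative cells, 47 higher and 2376 lower (98.06%), with a median of -0.686 over all genes. Among genes with at least 10 counts in both GFP-positive libraries, 7 were called, all lower. DESeq2 called 4152 and limma-voom 573. Leaving out either GFP-negative library gave 1293 or 1308, all of them lower, so that every rise named above lost its call, and leaving out either GFP-positive library gave 3970 or 4165.

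**Figure D3:**
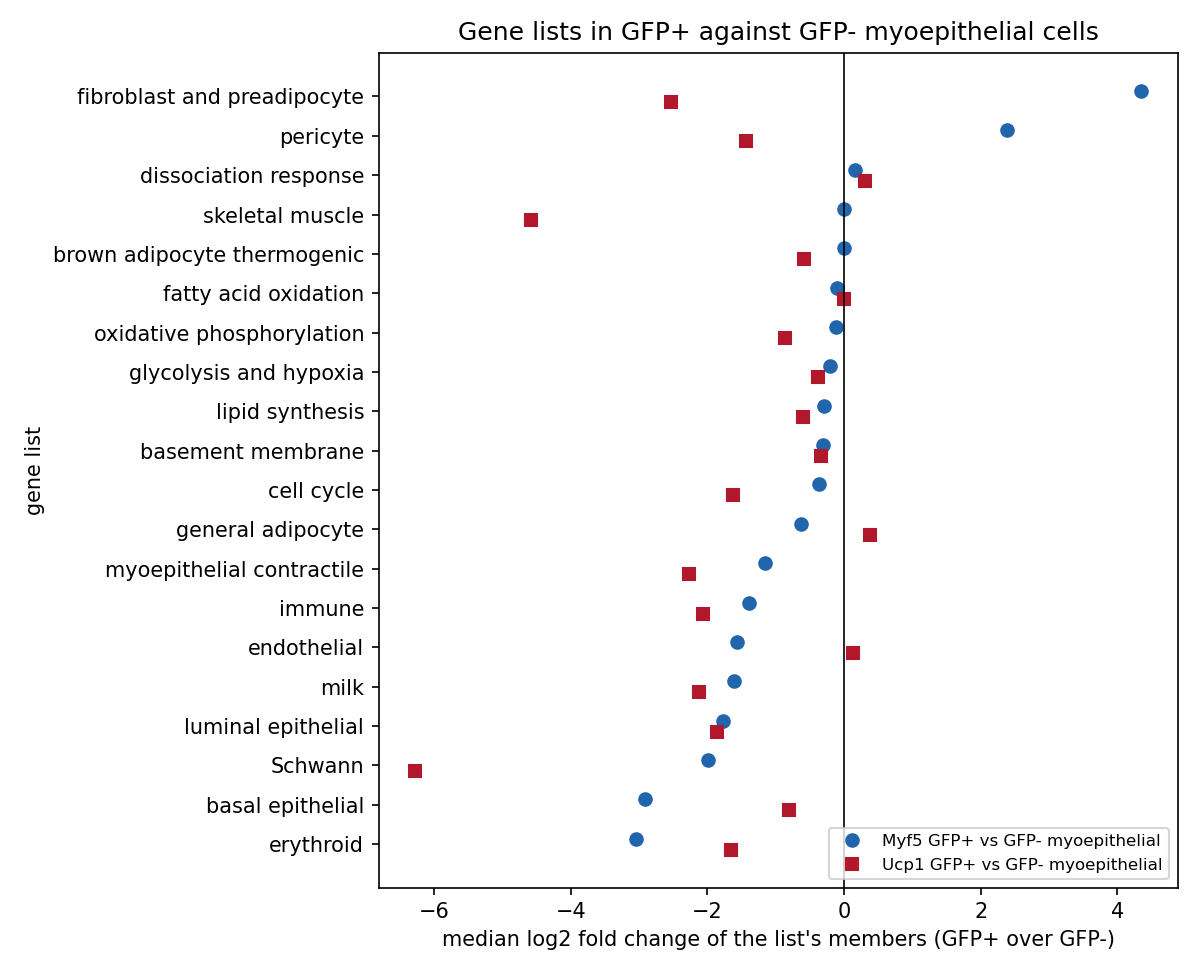
Median log2 of the 20 lists in GFP-positive over GFP-negative cells, with empty genes at their bound. The fibroblast and preadipocyte list was at 4.35 with the Myf5 label and -2.54 with the Ucp1 label.

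The third question was what the 2 labels share and where they differ. With both drivers pooled (n = 4 against 4), milk, contractile, basal and luminal genes lay lower in GFP-positive cells. Csn2 averaged 10250 ± 4336 against 40350 ± 12560 CPM (log2 -1.92, SE 0.56, edgeR adjusted p = 0.456), Cnn1 253 ± 86.0 against 1715 ± 638 CPM (log2 -2.67, SE 0.462, edgeR adjusted p = 0.315) and Cidea 152 ± 30.1 against 439 ± 114 CPM (log2 -1.47, SE 0.325, edgeR adjusted p = 0.315). Over the list alone, 12 milk members (median -1.77, adjusted p = 7.7e-15, and adjusted p = 0.083 with an estimated correlation), 6 contractile (-1.73, adjusted p = 1.2e-09 and 0.21), 4 basal (-2.05, adjusted p = 7e-05 and 0.28) and 5 luminal members (-1.56, adjusted p = 6e-06 and 0.069) were lower. Without overlap lay 10 of 16 milk, 7 of 17 contractile, 7 of 18 basal and 7 of 16 luminal genes, where chance gives 1.43% for a single gene. The share over all genes was not computed, and their median was also below 0 (-0.311). Lists of other cell types were also lower: immune (-1.56, 10 of 16 without overlap, adjusted p = 1.4e-07 and 0.16), erythroid (-2.22, 4 of 5, adjusted p = 1.2e-05 and 0.19) and Schwann (-4.98, 2 of 6, adjusted p = 0.00072 and 0.28). Higher were the dissociation response (0.355, adjusted p = 0.00022 and 0.21) and pericyte lists (0.546, adjusted p = 0.0044 and 0.65), the second value of each pair again with an estimated correlation, and 0 members of either lay without overlap. The pericyte result is not shared, as 9 of 10 members lay higher without overlap with the Myf5 label and 9 lower with the Ucp1 label. The basal result is shared only in part. Without overlap, 13 of 18 basal members lay lower and 1 higher with the Myf5 label, and 10 lower and 2 higher with the Ucp1 label. The median difference between drivers was 1.64 (Ucp1 minus Myf5, camera adjusted p = 0.0021, lost with an estimated correlation). With the Ucp1 label no basal member was called and camera pointed upward (above). The thermogenic list had a median of 0.419 and a mean of -0.643 (adjusted p = 0.85), and the fibroblast list a median of 0.715 (adjusted p = 0.088). edgeR called 0 of 13994 genes, with 691 at unadjusted p under 0.05, while DESeq2 called 588 (497 lower), and limma-voom 0. Without the Ucp1 GFP-positive libraries edgeR called 86, an effect that then comes from the Myf5 line alone.

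Tested directly, the GFP effect differed between drivers for 1861 genes, 1813 of them lower with the Ucp1 label. Dcn differed by a log2 of -7.13 and Col3a1 by -6.68 (edgeR adjusted p = 0.00424 and adjusted p = 0.00379), and Des, Has1 and C3 each had an adjusted p = 0.00198. Lipe differed upward with the Ucp1 label by 2.96 (edgeR adjusted p = 0.0142) and Dgat2 by 4.05 (edgeR adjusted p = 0.0302). Des, Has1, C3 and Dgat2 were named for their calls with the Ucp1 label, which this difference contains, so they give no separate support. The fibroblast list differed by a median of -6.90 with 7 members called (adjusted p = 2e-07, and adjusted p = 0.024 with an estimated correlation), the only list difference to hold with an estimated correlation. Among genes with at least 10 counts in both Ucp1 GFP-positive libraries, 38 differed (6 higher, 32 lower). DESeq2 gave 3096 and limma-voom 702, and leaving out 1 library gave 949 (a Myf5 GFP-negative one) to 3740 (a Ucp1 GFP-positive one). Across genes, the 2 label effects correlated at a Spearman of -0.0424 (49.2% of the same sign), and over the 8821 genes with a mean of at least 10 CPM at -0.133 (Pearson -0.247, 46.8% of the same sign; genes are not independent replicates). In the 4-library fits behind this, over the 16953 genes of the 12-library fit, edgeR called 123 genes higher and 11 lower with the Myf5 label and 87 higher and 2665 lower with the Ucp1 label. Of these, 0 were higher and 1 lower with both labels, where 0.631 and 1.73 would arise by chance. With genes filtered on its 4 libraries alone (14436 genes), the Myf5 fit gave 0 calls.

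Between mammary cells and brown adipocytes, genes with copies elsewhere in the genome and small RNA genes differed widely, and those named here were chosen after their values were seen. Gapdh, a glycolysis enzyme with 83.5% of its sequence shared with copies, averaged 681 ± 287 CPM in mammary and 10.7 ± 3.21 CPM in brown adipocyte libraries (SD, n = 8 and n = 4), and Ppia, a cyclophilin, 1039 ± 502 against 12.6 ± 0.945 CPM. Among genes of the mitochondrial chromosome, mt-Co2 averaged 7.13 ± 1.51 CPM in mammary and 28430 ± 13560 CPM in brown adipocyte libraries, and mt-Cytb 4122 ± 1160 against 46200 ± 20210 CPM. The ribosomal RNA genes mt-Rnr1 and mt-Rnr2 had 0 counts in every mammary library and averaged 3685 and 38240 CPM in brown adipocytes. No mammary library held a microRNA gene with a count, and brown adipocyte libraries held 71 to 134. Comparisons between the tissues below therefore cannot be separated from a possible difference in counting, nor from lactation and age. Counts of calls and some of the lists were repeated on genes of little shared sequence. Comparisons within a tissue are not touched by this.

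**Figure D4:**
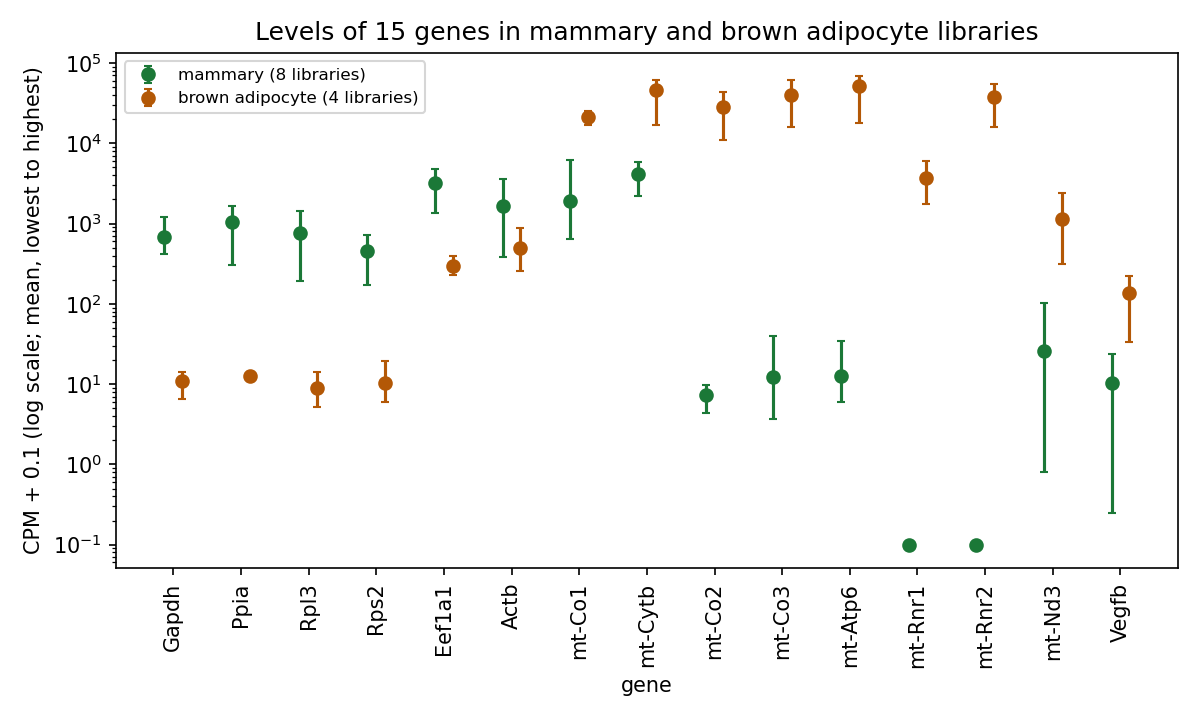
Mean CPM plus 0.1, with lowest and highest library, of 15 genes in 8 mammary and 4 brown adipocyte libraries. Gapdh averaged 681 CPM in mammary and 10.7 CPM in brown adipocyte libraries.

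The fourth question was how labelled myoepithelial cells compare with labelled brown adipocytes. Ucp1 was at least 215000-fold lower in Myf5 GFP-positive myoepithelial cells than in Myf5 brown adipocytes (14500 ± 2734 CPM there; edgeR adjusted p = 0.000965) and at least 48590-fold lower in the Ucp1 line (2130 ± 1669 CPM; edgeR adjusted p = 0.000812; SD, n = 2 each). Elovl3, a fatty acid elongase of brown fat (ENSMUSG00000038754, chromosome 19, 46131897 to 46135694), fell at least 30100-fold and at least 20870-fold, and Otop1 (ENSMUSG00000051596, chromosome 5, 38275972 to 38304217) at least 8401-fold and at least 4910-fold. In the other direction, Csn2 rose at least 75030-fold and at least 61990-fold, uncertain in size because casein genes share sequence. Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) fell at least 19260-fold in the Myf5 line and by a log2 of -5.20 in the Ucp1 line (SE 1.08, edgeR adjusted p = 0.0104; 14.8 ± 3.17 against 543 ± 393 CPM). Cidea, by contrast, was still measurable in myoepithelial cells, 145 ± 37.2 against 3920 ± 255.3 CPM (log2 -4.76, SE 0.647, edgeR adjusted p = 0.00192) and 160 ± 33.2 against 1729 ± 1292 CPM (log2 -3.43, SE 0.608, edgeR adjusted p = 0.00403). Its mean was higher in GFP-negative than in GFP-positive myoepithelial cells of both lines (above), so it was not particular to labelled cells.

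Contractile and basal genes separated the same groups. In the Myf5 line, Acta2 rose from 2.44 ± 0.343 CPM in brown adipocytes to 1562 ± 21.8 CPM (log2 9.32, SE 1.15, edgeR adjusted p = 0.00129) and Tagln from 3.92 ± 1.53 to 939 ± 213 CPM (log2 7.91, SE 0.743, edgeR adjusted p = 0.000701). In the Ucp1 line, Cnn1 (ENSMUSG00000001349, chromosome 9, 22099216 to 22109630) rose from 2.04 ± 2.29 to 290 ± 39.8 CPM (log2 7.13, SE 0.982, edgeR adjusted p = 0.00139) and Acta2 from 66.1 ± 24.4 to 764 ± 876 CPM (log2 3.53, SE 0.877, edgeR adjusted p = 0.0176). Des fell at least 1188-fold there, against the list. Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) rose at least 132-fold and at least 632-fold, and Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029) at least 350-fold and at least 601-fold. The contractile list had 12 called members of 17, all higher, in the Myf5 line (median 6.44, or 5.70 at the bounds, adjusted p = 2.2e-10, and adjusted p = 0.074 with an estimated correlation) and 5 higher and 1 lower in the Ucp1 line (1.94, adjusted p = 0.00012 and 0.29). The basal list had 8 higher (5.87, or 5.15 at the bounds, adjusted p = 6.6e-06 and 0.11) and 7 higher (3.46, adjusted p = 1.1e-08 and 0.12).

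Fat and mitochondrial energy genes were lower in myoepithelial cells. Not repeated on genes of little shared sequence were the fatty acid oxidation, oxidative phosphorylation, lipid synthesis, glycolysis, dissociation response, basement membrane and skeletal muscle lists. In the thermogenic list 9 members fell in the Myf5 line (median -6.67, adjusted p = 1.1e-08, and adjusted p = 0.073 with an estimated correlation) and 10 in the Ucp1 line (-6.91, or -4.10 at the bounds, adjusted p = 0.00015 and 0.29). General adipocyte genes that fell numbered 13 and 8 (medians -5.69 and -2.92), fatty acid oxidation genes 15 and 14 (-5.05 and -3.19) and oxidative phosphorylation genes 17 and 19 (-3.75 and -3.58). By camera these 3 lists were lower in both lines, with adjusted p = 0.066, adjusted p = 0.073 and adjusted p = 0.073 in the Myf5 line and adjusted p = 0.39, adjusted p = 0.37 and adjusted p = 0.29 in the Ucp1 line with an estimated correlation. Milk genes were higher in both (medians 13.3 and 14.2, or 9.70 and 9.53 at the bounds), and so were fibroblast (7.0, 11 called) and pericyte genes (5.74, 7 called) in the Myf5 line. Other lists moved too. In the Myf5 line these were dissociation response (3.28, 10 called, 13 of 14 without overlap, adjusted p = 1.5e-07), immune (3.80, 7 called), endothelial (3.14, 6 called), luminal (4.91, or 4.70 at the bounds, 5 called) and basement membrane (2.49, 5 called), all higher, and lipid synthesis (-5.97, 12 called) and glycolysis (-2.80, 7 called), both lower, with an adjusted p = 0.074 to 0.2 with an estimated correlation. In the Ucp1 line dissociation response (0.776, 3 called, adjusted p = 8e-05), luminal (5.90, or 5.50 at the bounds, 6 higher and 1 lower), endothelial (1.27, 1 called) and basement membrane (1.77, or 1.56 at the bounds, 3 called) were higher, and lipid synthesis (-3.25, 7 called) and skeletal muscle (-8.78, or -6.18 at the bounds, 6 called) lower, with an adjusted p = 0.12 to 0.41 with an estimated correlation. Some adipocyte genes were close between the tissues in the Ucp1 line: Pparg, the adipogenic nuclear receptor, at 277 ± 4.71 against 377 ± 83.5 CPM (log2 -0.44, edgeR adjusted p = 0.448) and Cd36, a fatty acid transporter, at log2 0.35 (edgeR adjusted p = 0.573). Of all tissue list calls, only milk, fibroblast and pericyte in the Myf5 line and milk in the Ucp1 line held with an estimated correlation (adjusted p = 0.037, adjusted p = 0.03, adjusted p = 0.037 and adjusted p = 0.024).

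Pooled over both drivers (n = 4 against 4), Ucp1 was at least 312900-fold lower (edgeR adjusted p = 0.00443), Myh11, smooth muscle myosin, rose by a log2 of 7.41 (SE 0.83, edgeR adjusted p = 0.00443) and Cnn1 by 6.85 (SE 0.794, edgeR adjusted p = 0.00443). Krt17, Krt5 and Krt15 rose at least 940-fold, at least 740-fold and at least 695-fold. Contractile and basal genes each had 7 called members, all higher (medians 3.81 and 4.21), and thermogenic genes 8, all lower (-4.61). With an estimated correlation, these 3 had an adjusted p = 0.2, adjusted p = 0.089 and adjusted p = 0.15.

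edgeR called 3352 genes in the Myf5 tissue comparison (1854 higher, 1498 lower), 4717 in the Ucp1 line (905 higher, 3812 lower) and 1847 of 12899 pooled (650 higher, 1197 lower). On genes of little shared sequence these were 1505, 2165 and 464, and the contractile, basal and thermogenic medians kept their direction (7.18, 5.70 and -6.98 in the Myf5 line, 1.87, 3.20 and -7.25 in the Ucp1 line). DESeq2 called 5618 and 4898 genes in the Myf5 and pooled comparisons, and limma-voom 5998, 2061 and 3666. With only the compared groups in the fit, the Ucp1 line gave 0 calls, and over genes with at least 10 counts in both Ucp1 GFP-positive libraries 1766. Leaving out 1 brown adipocyte library gave 1163 or 1480 in the Myf5 line, 2920 or 2194 in the Ucp1 line and 374 to 1104 pooled, leaving out the first Myf5 GFP-positive library 1752, and leaving out the 2 Ucp1 GFP-positive libraries 6199 in the Myf5 line and 4934 pooled (then from the Myf5 line alone).

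The fifth question was whether labelled myoepithelial cells lie toward brown adipocytes relative to unlabelled ones. The signature gave lower levels of mammary genes, while its brown adipocyte side rested on few testable genes and changed with the gene set. Genes lower in brown adipocytes of the Myf5 line had a median log2 of -2.39 in Ucp1 GFP-positive over GFP-negative cells (13% above 0, all-gene median -0.504, adjusted p = 1.6e-06, and adjusted p = 0.1 with an estimated correlation). Those chosen in the Ucp1 line had -1.72 with the Myf5 label (22.9% above 0, all-gene median -0.0636, adjusted p = 3.9e-12 and 0.071). Of 200 genes higher in brown adipocytes only 25 and 6 could be tested, with medians of 0.747 (adjusted p = 0.12) and -0.526 (adjusted p = 0.21). On genes of little shared sequence, 82 and 98 could be tested, with medians of -0.43 (adjusted p = 0.48) and 0.62 (67.3% above 0, adjusted p = 0.011, and adjusted p = 0.097 with an estimated correlation). Over all genes, Myf5 GFP-positive myoepithelial libraries correlated at r = 0.831 with GFP-negative ones and r = 0.557 with brown adipocytes, and Ucp1 GFP-positive ones at r = 0.735 and r = 0.630. GFP-negative libraries correlated with brown adipocytes of their line at r = 0.575 (Myf5) and r = 0.717 (Ucp1). Labelled libraries also correlated less with each other (r = 0.845 in the Myf5 and r = 0.690 in the Ucp1 line) than unlabelled ones (r = 0.904 and r = 0.984). Such spread lowers the correlation with any other group. This measure therefore cannot tell whether labelled cells lay closer to brown adipocytes than unlabelled ones.

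The last question was how the 2 drivers differ within a cell group, where line and driver cannot be separated. In brown adipocytes, the Ucp1 line held more RNA of vascular, mural and dissociation response genes and less of adipocyte and energy genes in general. Hadha, a subunit of the mitochondrial trifunctional enzyme (ENSMUSG00000025745, chromosome 5, 30118304 to 30155162), fell from 1845 ± 82.5 CPM in the Myf5 line to 200 ± 7.13 CPM (log2 -3.21, SE 0.377, edgeR adjusted p = 0.017), and Lipe (ENSMUSG00000003123, chromosome 7, 25379527 to 25398710) from 1272 ± 68.0 to 254 ± 133 CPM (log2 -2.32, SE 0.452, edgeR adjusted p = 0.0452). Fabp3 and Pfkfb3 were the other 2 falls (-3.18 and -2.83). Acta2 rose from 2.44 ± 0.343 to 66.1 ± 24.4 CPM (log2 4.76, SE 0.945, edgeR adjusted p = 0.0483), the pericyte genes Abcc9 and Rgs4 by 5.61 and 5.37, the antigen presentation gene Cd74 by 3.99 and the immediate-early gene Egr1 by 3.68 (edgeR adjusted p = 0.0288). Mfsd6 and Selp, an endothelial adhesion molecule, rose at least 151-fold and at least 131-fold. Ucp1 averaged 2130 ± 1669 against 14500 ± 2734 CPM without a call (edgeR adjusted p = 0.219).

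All 14 endothelial members lay higher without overlap in Ucp1 brown adipocytes (0 called, 14 over the list alone, median 4.30, adjusted p = 7.5e-14, and adjusted p = 0.11 with an estimated correlation). Beside them were pericyte (4.04, 2 called), immune (2.71, 1 called), erythroid (3.37, 0 called) and dissociation response genes (2.39, 4 called). Lower lists were fatty acid oxidation (-1.75, 1 called, 13 over the list alone, adjusted p = 7.5e-14 and 0.11), oxidative phosphorylation (-1.19, 0 called) thermogenic (-1.59, 0 called, adjusted p = 4.9e-07 and 0.11), lipid synthesis (-1.30, all 14 below 0, adjusted p = 1.7e-06 and 0.13), general adipocyte (-1.46, 1 called, adjusted p = 8.2e-06 and 0.12), and glycolysis and hypoxia (-0.803, adjusted p = 0.00037 and 0.2). Contractile (2.52, or 2.06 at the bounds, 2 called, adjusted p = 0.00015 and 0.21) and basal genes (0.801, 0 called, adjusted p = 0.043 and 0.49) were higher. No list call between the brown adipocyte lines held with an estimated correlation, where the smallest was adjusted p = 0.11. edgeR called 223 genes (219 higher, 4 lower), RLE factors 135, DESeq2 1486, limma-voom 2908, a test against a 2-fold change 79, only the compared groups 755, and a fit without the Ucp1 GFP-positive myoepithelial libraries 929 (829 higher, 100 lower). Leaving out the first library of either line gave 0 calls, and leaving out the second of the Myf5 or of the Ucp1 line gave 349 or 133.

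GFP-positive myoepithelial cells of the Ucp1 line held less RNA of stromal genes than those of the Myf5 line. Sfrp4, a secreted Wnt modulator, and Has1 fell at least 74740-fold and at least 37360-fold, from 3277 ± 1055 and 1638 ± 260 CPM (SD, n = 2 each; edgeR adjusted p = 0.00508 and adjusted p = 0.00088), and Dcn fell from 7214 ± 5153 to 69.1 ± 15.5 CPM (log2 -6.71, SE 0.921, edgeR adjusted p = 0.00162). Adipoq rose at least 219-fold, Dgat2 by a log2 of 4.37 (SE 0.784, edgeR adjusted p = 0.00508), Lipe by 2.99 and the integrin gene Itga6 by 2.87. The fibroblast list had 6 called members, all lower (-4.60, adjusted p = 6.7e-06, and adjusted p = 0.062 with an estimated correlation), and the general adipocyte list 5 higher and 1 lower (1.80, adjusted p = 6.7e-06 and 0.33). Endothelial (1.96, 1 called, 10 of 14 without overlap, adjusted p = 0.00017), basal (1.07, 2 called, adjusted p = 0.0098) and dissociation response genes (0.482, 0 called, adjusted p = 0.0098) were also higher, each with an adjusted p = 0.63 with an estimated correlation. edgeR called 2934 genes, 2572 of them lower. DESeq2 called 5382 and limma-voom 660, only the compared groups gave 0, genes with at least 10 counts in both Ucp1 GFP-positive libraries 885, and leaving out 1 of these libraries 4983 or 4962.

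GFP-negative myoepithelial cells of the 2 lines were compared last, which shows the line difference without the label. Col3a1 averaged 1505 ± 231 CPM in the Ucp1 and 152 ± 32.9 CPM in the Myf5 line (log2 3.31, SE 0.723, edgeR adjusted p = 1), and the pericyte list was higher in the Ucp1 line (median 1.83, 4 members over the list alone, adjusted p = 3e-07, and adjusted p = 0.082 with an estimated correlation). Also higher there were skeletal muscle (2.82, or 2.48 at the bounds, adjusted p = 0.00069, and adjusted p = 0.43 with an estimated correlation), fibroblast (0.965, adjusted p = 0.0046 and 0.16), basement membrane (0.552, adjusted p = 0.0046 and 0.6), thermogenic (0.783, or 0.728 at the bounds, adjusted p = 0.0094 and 0.6), dissociation response (0.719, adjusted p = 0.0094 and 0.62) and general adipocyte genes (0.674, adjusted p = 0.036 and 0.62), and lower was oxidative phosphorylation (-0.441, adjusted p = 0.00069 and 0.6). This bears on the driver difference of the GFP effect. edgeR called 0 of 16953 genes with 604 at unadjusted p under 0.05, DESeq2 43 and limma-voom 90.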

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

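The tests of single genes below were listed after the text had named those genes, and the tests of lists and splits were chosen beforehand. Des, Has1, C3, Ackr1, Gja5, Tmem63a, Tlr2, Tmem86a, F3 and Tmem115 were named as the largest falls, to 0 counts, with the Ucp1 label. Hp, Skap1, Dgat2 and Atm were named as rises there. The difference between drivers contains that comparison, so the passing of these genes was partly fixed in advance and gives no separate support. The GFP effect differed between the Myf5 and Ucp1 lines for 1861 genes. By median log2 difference (Ucp1 minus Myf5), lists that differed were basal epithelial (1.64), general adipocyte (0.969), fibroblast and preadipocyte (-6.90), endothelial (1.60), pericyte (-3.30) and Schwann (-7.61). These are medians of fitted values, and with groups at 0 set to their bound the general adipocyte median is 0.928 (2 of 18 members affected), the Schwann median -6.88 (5 of 8) and the fibroblast median unchanged at -6.90 (2 of 14). Of these only the fibroblast list held with an estimated correlation (adjusted p = 0.024), and the others had an adjusted p = 0.39 or more.

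By edgeR adjusted p for the difference of the GFP effect between drivers, named genes that differed were C3, Des, Dpt, F3, Has1, Tmem115 and Tmem86a (each 0.00198), Lum (0.0021), Tmem63a (0.0023), Gja5 (0.00275), Col3a1 (0.00379), Dcn (0.00424), Dpp4 (0.00535), Dio2 and Hp (each 0.00568), Lhx8 (0.00618), Ackr1 (0.00673), Thy1 (0.00779), Sfrp4 (0.00999), Tlr2 (0.0102), Lipe (0.0142), Ptprc (0.0155), Rgs4 (0.0184), Aloxe3 (0.0223), Skap1 (0.0232), Dgat2 (0.0302), Myocd (0.0317), Zic1 (0.0325), Atm (0.0439).

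Splits of the 8 pooled libraries into 4 against 4 show only whether chance can be excluded. For the GFP label the real split gave 0 calls (highest other 1), so all 35 of 35 splits had at least as many by construction, and the splits decide nothing. For myoepithelial cells against brown adipocytes, 1 of 35 splits, the real one, gave 1847 calls and the highest other 0.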

How the results depend on the processing

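Every group had 2 libraries, and where 1 was left out, the lone library of that arm is assumed to vary like the other groups. The cause of the shifts below was not tested. Settings added after the data were seen are the fit without the 2 Ucp1 GFP-positive myoepithelial libraries, genes with 10 counts in both of them, and genes of little shared sequence. Over all settings, 88 counts of calls stayed within 1.5 times and 67 moved beyond. For list results, 990 stayed the same, 30 moved, 26 were stronger and 109 weaker, and for single genes 6049 stayed the same, 29 moved, 27 were stronger and 1120 weaker. The higher signature, without a call in the fit with all libraries, changed the sign of its median (values below). The Myf5 label, pooled label and GFP-negative driver counts stayed at 0 with any 1 library of the compared groups left out.

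With DESeq2, calls numbered 724 (Myf5 label), 4152 (Ucp1 label), 588 (label pooled), 3096 (difference between drivers), 5618 (Myf5 tissue), 4898 (tissue pooled), 1486 (brown adipocyte driver), 5382 (GFP-positive driver) and 43 (GFP-negative driver). With limma-voom they were 197 (Myf5 label), 573 (Ucp1 label), 702 (difference), 5998 (Myf5 tissue), 2061 (Ucp1 tissue), 3666 (tissue pooled), 2908 (brown adipocyte driver), 660 (GFP-positive driver) and 90 (GFP-negative driver). The brown adipocyte driver count was 135 with RLE factors and 79 against a fold of 2. With only the compared groups in the fit, counts were 1187 (difference), 0 (Ucp1 tissue), 755 (brown adipocyte driver) and 0 (GFP-positive driver). The contractile median with the Myf5 label was -1.17 without filtering (adjusted p = 0.088) and -1.16 with milk and mitochondrial genes removed (adjusted p = 0.05). With an estimated correlation, calls were lost for the basal (-2.91, adjusted p = 0.16) and contractile lists (-1.16, adjusted p = 0.62) with the Myf5 label and for the contractile list with the Ucp1 label (-2.265, adjusted p = 0.77). The pericyte call with the Myf5 label, kept over all 12 libraries with an estimated correlation, was lost that way without the 2 Ucp1 GFP-positive ones (adjusted p = 0.067).

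Other list calls that were lost, by camera at the preset correlation, include the following. With the Ucp1 label, RLE factors ended the milk, immune and endothelial calls (adjusted p = 0.051 each). Leaving out the first Ucp1 GFP-positive library ended the contractile (adjusted p = 0.097) and milk calls (0.17), and leaving out the second ended the milk (0.4), immune (0.4), endothelial (0.53) and general adipocyte calls (0.39). Leaving out the first Ucp1 GFP-negative library ended the immune (0.051) and endothelial calls (0.068). With the Myf5 label, the contractile and general adipocyte calls were lost without either GFP-positive library (0.38 and 0.13 for the first, 0.17 and 0.089 for the second) and without the second GFP-negative one (0.52 and 0.078). The pooled pericyte call was lost without any 1 of the 4 Myf5 myoepithelial libraries (0.064 to 0.23), with a median below 0 without either GFP-negative one (-0.2007 and -0.2458). Without the second Myf5 GFP-negative library, the GFP-negative driver calls for fibroblast (0.58), thermogenic (0.27) and general adipocyte genes (0.45) were lost, and the basal call of the GFP-positive driver comparison was lost without the first Ucp1 GFP-positive library (0.13). Between brown adipocytes of the 2 drivers, the basal call was lost without the second Myf5 library (0.096) or either Ucp1 library (0.094 and 0.052). For Ucp1 tissue, the general adipocyte call was lost without the first GFP-positive myoepithelial (0.27) or the second brown adipocyte library (0.079), and the endothelial call without the second GFP-positive myoepithelial library (0.063).

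Samples of the groups share only a replicate number. Their deviations from group means correlated at 0.32 between Myf5 GFP-positive and GFP-negative cells and at -0.0784 to 0.072 in all other pairs of groups, and the labels do not say whether samples of the same number are paired by animal. With the replicate block, calls numbered 1251 (Ucp1 label), 957 (difference), 2032 (Myf5 tissue), 2775 (Ucp1 tissue), 353 (tissue pooled) and 76 (brown adipocyte driver), the contractile median was -1.06 with the Myf5 label (adjusted p = 0.18) and the basal median -1.69 with the Ucp1 label (adjusted p = 0.99).

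Without the 2 Ucp1 GFP-positive libraries, calls numbered 232 (Myf5 label), 6199 (Myf5 tissue), 929 (brown adipocyte driver), 86 (label pooled) and 4934 (tissue pooled), both pooled effects then coming from the Myf5 line alone. Over genes with 10 counts in both, they were 7 (Ucp1 label), 1766 (Ucp1 tissue), 38 (difference) and 885 (GFP-positive driver), with a basal median of -0.62 for the Ucp1 label (adjusted p = 0.13). On genes of little shared sequence, calls numbered 1505 (Myf5 tissue), 2165 (Ucp1 tissue) and 464 (tissue pooled), the higher signature went from a median of 0.747 to -0.435 (tested in Ucp1) and from -0.526 to 0.62 (tested in Myf5), and the correlation of Myf5 GFP-positive with GFP-negative libraries exceeded that with brown adipocytes by 0.220 (0.2745 over all genes). With the milk list and genes over 1000 CPM left out, the higher signature tested in Ucp1 had a median of -3.748, and tested in Myf5 it had 0 testable genes. For genes with a mean of at least 10 CPM, the correlation of label effects was -0.133.

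Leaving out each library in turn gave 1293 to 4165 calls for the Ucp1 label, 949 to 3740 for the difference between drivers, 1163 to 2524 for Myf5 tissue, 2194 to 6400 for Ucp1 tissue, 374 to 2230 for tissue pooled, 0 to 349 for the brown adipocyte driver and 2537 to 4983 for the GFP-positive driver. Medians ran from -1.632 to -0.1102 for the contractile list with the Myf5 label, and with the Ucp1 label from -1.616 to -0.7745 (basal), -3.712 to -1.849 (contractile) and -4.396 to -0.2107 (thermogenic).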

Other observations

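The tests in the paragraphs on patterns were chosen after the pattern was seen, except those on random loss of transcripts and on counting rules, which were fixed before their values were computed. Vascular and mural genes also varied within brown adipocytes. In Ucp1 over Myf5 brown adipocytes, Pgf, a placental growth factor, rose at least 65.2-fold to 10.2 ± 6.77 CPM (n = 2; edgeR adjusted p = 0.036), and the connexin gene Gja5 at least 73.6-fold (edgeR adjusted p = 0.0323). Within labelled myoepithelial cells, Scd1, a desaturase of fat synthesis, rose from 82.6 ± 3.50 CPM in the Myf5 to 802 ± 628 CPM in the Ucp1 line (log2 3.28, SE 0.802, edgeR adjusted p = 0.0212). Aloxe3, a lipoxygenase of epidermis, rose at least 336-fold in the same comparison (edgeR adjusted p = 0.00679).

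The first pattern is the higher level of stromal genes with the Myf5 label. Stromal cells in the sorted fraction could account for it, although the gate (lineage-negative, CD24-positive, CD29-high) is meant to remove CD24-negative stroma, and the 92.9% of fibroblast list members that lay higher without overlap only restate the pattern. A lower share of the main cell type alone would raise other cell types together. The endothelial list lay lower (median -1.57), but 9 of 10 pericyte members lay higher without overlap. This cannot exclude it, because lineage depletion is meant to remove endothelial cells and the endothelial call was lost with an estimated correlation. Milk and mitochondrial reads in the library totals are excluded because these shift every gene alike. The fibroblast median lay 4.40 above that of all tested genes (list lower quartile 3.41, all-gene upper quartile 0.551). A stromal-like state of labelled myoepithelial cells might also account for it, and bulk libraries cannot separate this from a mixture (basal median -2.91). Single-cell profiles of the sorted cells, with Dcn and Krt14 scored in the same cells, would tell.

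The second pattern is that 98.06% of genes called with the Ucp1 label were lower. Random loss of transcripts at low input could account for it, but its test decides nothing: genes under 3 counts in both GFP-positive libraries numbered 1.38 times the product of the separate rates, which could not have passed 2.66 at these rates, and where there was more room 161 genes were shared against 78.49 (20 to 40 CPM in GFP-negative cells) and 26 against 7.97 (40 to 80 CPM). Lower sequencing depth is excluded, since GFP-negative libraries thinned to the same total still held at least 1.73 times as many genes. A narrower transcriptome of the Ucp1-labelled cells is also possible, and the 7 calls among well-covered genes cannot separate it from low input. Until repeated with more cells, 0 counts with the Ucp1 label should not be read as absence from the cells. This covers Des, Has1 and C3 and the thermogenic genes Otop1, Dio2, Ucp1, Slc27a2 and Lhx8.

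The third pattern is the difference between mammary and brown adipocyte libraries in genes with copies elsewhere in the genome and in small RNA genes. Reads counted by different rules in the mammary and brown adipocyte files could account for it: of genes at 0 in all mammary and at least 10 CPM in all brown adipocyte libraries, 75.6% (31 of 41) were small RNA or antisense genes or mostly shared sequence, against 5.05% of the 6291 other genes at that brown adipocyte level. A difference between the tissues alone is excluded for mitochondrial ribosomal RNA, with 0 counts of mt-Rnr1 and mt-Rnr2 in mammary libraries that held at least 2188 CPM of mt-Cytb. For ribosomal protein genes it remains open, as medians for genes of high and low shared sequence differed by 0.921 with overlapping quartiles. Recounting all reads with 1 rule would tell.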
